A study of Mus musculus with 21 samples.

How the data were processed

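RNA of the lumbar spinal cord was sequenced from mice with both, 1 or no copies of the C9orf72 ortholog 3110043O21Rik. Per the labels' protocols, total RNA was extracted from frozen tissue, and libraries were made by Illumina (3 months) or Ion Torrent (17 months) protocols. Groups were taken from the genotype labels, with 3 libraries per genotype at 3 months and 4 at 17 months. The series' design text counts mice, so a library was treated as a mouse.

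The authors deposited 1 table of RPKM values per age. Whether these are RPKM or FPKM was not stated. Values were not whole numbers, library totals differed, and values multiplied by annotated gene length in kilobases summed to 956445 to 966820 per library at 3 months and to 975092 to 1057722 at 17 months. TopHat2 2.0.8b and Partek are named, per the submitters' processing notes. The builds mm9 and mm10 are named there as well, without saying which table used which. The annotation, filters, strand use and counting mode are not given in the sources used here. Some values lay between 0 and the worth of a read, so reads were apportioned by estimation, and near-identical genes such as the globins cannot be told apart. Tests on recovered whole reads were therefore not made. At 3 months 14 tested genes in 6 sets, and at 17 months 12 in 5 sets, had identical values in every library. Rows whose names had been converted to dates (26 per table, 0.272% and 0.264% of the total) were left out. The tables then held 19747 and 20153 genes, and 0 columns of values were left unused.

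Read depth was unknown. Whole-number ratios between low values of a gene gave the relative depth of libraries, but no counting error of single values. Ages were never pooled, because they differ in instrument and table. The design had allowed for either counts or normalized values, and the test written for normalized values was used.

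Genes at 0.5 RPKM or more in at least 3 (3 months) or 4 (17 months) libraries were tested on log2(RPKM + 0.5) with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with trend and robust empirical Bayes, all 3 genotypes in a model per age, two-sided, Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate changes of low genes. The target and list means were also compared by exact two-sided permutation tests. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, adjusted over the lists of a comparison. The lists, fixed before the data were examined, covered lysosome, autophagy and C9orf72 partners, homeostatic and activated microglia, interferon response, antigen presentation, complement and Fc receptors, inflammatory cytokines and NF-kB targets, astrocytes, reactive astrocytes, motor neurons, synapses, oligodendrocytes and their precursors, endothelium, Schwann cells, dorsal root ganglion, meninges, erythroid, T and NK, B and plasma and infiltrating myeloid cells, skeletal muscle, immediate early genes, heat shock and ER stress, cholesterol synthesis, ALS and FTD genes, mitochondrially encoded, ribosomal protein, sex-linked and locus genes. Lists with fewer than 3 tested members were described only. Gene positions came from the GRCm38 annotation. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

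The rule for named genes was also fixed beforehand. It takes the target, then up to 10 genes per direction with the largest changes past the threshold, with groups that do not overlap and a group mean of at least 1 RPKM. Where fewer than 3 passed, the 3 with the smallest p were named as not past the threshold, and clone names were not named. Up to 4 members with the smallest p were named per list. Some members that the rule would name are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

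The model was tested on simulated data with 50 genes changed per fold size. For null against wild type at 3 months (13992 genes) 96% of genes changed by 0.5 on the log2 scale were recovered, and 100% at 1. At 17 months (14164 genes) 70% and 92% were recovered, with 6 false calls at each age. Both shifted lists were called and 0 others. The simulated genes varied independently of each other and no simulated library stood apart, so these rates need not hold for the real libraries. Other groupings of the real null and wild type libraries called up to 9 lists at 3 months and up to 17 at 17 months. Alternatives varied the pseudocount (0.1 or 1), the filter, the normalization, the limma settings, library weights, a sex-linked covariate at 17 months, the groups fitted and each library left out. Removal of a length and GC trend, removal of both libraries that stood apart and combinations with array weights were added after seeing the data. For gene lists, array weights, median centring and the sex-linked covariate were added then as well.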

Results

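RNA was measured in the lumbar spinal cord of C57BL/6 mice with 2, 1 or 0 working copies of 3110043O21Rik, the mouse ortholog of C9orf72, a gene whose repeat expansion is a known cause of amyotrophic lateral sclerosis and frontotemporal dementia. The groups are called wild type, heterozygous and null here. At 3 months each genotype had 3 libraries (Illumina), and at 17 months each had 4 (Ion Torrent), which gave 21 libraries in all. The comparison asks how the spinal cord transcriptome differs when 1 or both copies are lost. The series title names macrophages and microglia as its subject. Read totals were unknown. The deposited RPKM values of a library summed to between 287670 and 293260 at 3 months and to between 296323 and 358802 at 17 months. Whole-number ratios between low values of a gene, which held for 58.6% to 67.8% of the ratios per library, put the deepest 3 month library at 2.116 times the shallowest, and the deepest 17 month library at 1.356 times. The share of such ratios that chance alone would give was not worked out, so these depths are approximate. Pairs of libraries correlated at 0.995 to 0.998 across genes at 3 months and at 0.972 to 0.997 at 17 months, and 0 pairs were identical.

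All 9 libraries at 3 months expressed Y-linked genes. At 17 months Xist, the transcript that silences an X chromosome in females, was high in wild type replicate 3, heterozygous replicate 1 and null replicates 2 and 4 (44.6, 38.9, 25.7 and 36.0 RPKM), so the null group held 2 such libraries and each other group 1. Null replicate 2 and wild type replicate 4 stood apart at 17 months. The first principal component held 43.6% of the variance and placed null replicate 2 at 38.0, and the second held 17.9% and placed wild type replicate 4 at -23.2.

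The targeted gene followed the labels in every library. 3110043O21Rik lies on the minus strand of chromosome 4 from 35191285 to 35226175 in GRCm38 and is annotated as protein coding. At 3 months it measured 12.1 ± 0.0906 RPKM in wild type, 6.40 ± 0.228 in heterozygous and 0.522 ± 0.0904 in null cords (mean ± SD, n = 3 each). Heterozygous cords thus held 52.7% of the wild type level and null cords 4.30%. The null difference was -3.63 on the log2(RPKM + 0.5) scale (SE 0.06, limma adjusted p = 3.33e-12), and the heterozygous difference was -0.87 (SE 0.06, limma adjusted p = 0.000102). An exact two-sided permutation test gave p = 0.1 for each, the smallest that 3 against 3 libraries allow. At 17 months the gene measured 13.9 ± 0.451 RPKM in wild type, 7.51 ± 0.165 in heterozygous (54.0%) and 1.25 ± 0.591 in null cords (8.98%, n = 4 each). The null difference was -3.11 (SE 0.18, limma adjusted p = 4.49e-06). The heterozygous difference of -0.85 (SE 0.18) had an unadjusted limma p of 0.000500 and did not pass adjustment over all genes in the model of 3 genotypes, but passed with only the 2 groups fitted (limma adjusted p = 3.73e-05). The exact permutation p was 0.0286 for both, the smallest that 4 against 4 libraries allow. Single null libraries kept between 3.48% and 4.93% of the wild type mean at 3 months and between 4.17% and 12.99% at 17 months.

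**Figure D1:**
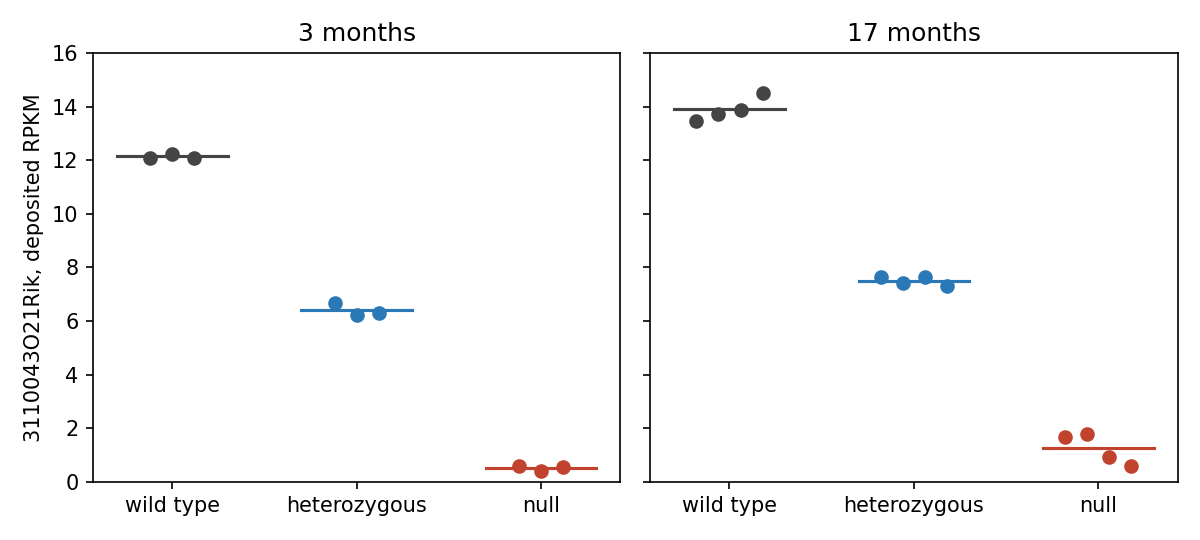
Deposited RPKM of 3110043O21Rik in each library (points) with the group mean (bars), by genotype and age. Heterozygous libraries sit near 52.7% of the wild type mean at 3 months and 54.0% at 17 months, and null libraries lie below both groups at each age.

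At 3 months, null cords were lower in Plekhm2 along with the target itself. Plekhm2, an adaptor that links lysosomes to kinesin, fell from 42.8 ± 1.75 to 34.9 ± 1.09 RPKM (n = 3 each, log2 difference -0.29, SE 0.03, limma adjusted p = 0.0141). Its highest null library measured 35.9 RPKM and the lowest library of the other genotypes 41.5. These were the 2 genes past the threshold of 13972 tested, and 997 genes had an unadjusted limma p under 0.05. The Plekhm2 call was lost with no filter on low values, with limma without trend and robust fit, with only the 2 groups fitted, and without wild type replicate 3, null replicate 2 or null replicate 3 (log2 difference -0.27 to -0.30, limma adjusted p from 0.0618 to 0.322). Genes with the smallest p that did not pass were Igfbp7, a secreted protein of vessel walls (13.8 against 10.96 RPKM, log2 difference 0.31, SE 0.05, limma adjusted p = 0.149), the lactate dehydrogenase gene Ldha (0.24, SE 0.04) and the cell cycle regulator Rgcc (0.38, SE 0.07) on the higher side. On the lower side were the GM-CSF receptor subunit Csf2ra (-0.30, SE 0.06), the tubulin glycylase Ttll3 (-0.33, SE 0.07) and the imprinted neuronal gene Nnat (-0.24, SE 0.05).

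Without null replicate 1 the count at 3 months was 8. Of the added genes 5 were chosen for description after their values were seen, because they are neighbours: Sfi1, Drg1, Eif4enif1, Patz1 and Pik3ip1 lie between 3.13 and 3.34 Mb of chromosome 11 in GRCm38. In null replicates 2 and 3 these genes measured 0.608 to 0.703 of the wild type mean, and in null replicate 1 they measured 0.968 to 1.06. Drg1, for example, was at 31.4 and 31.6 RPKM in null replicates 2 and 3 and at 46.9 RPKM in null replicate 1, against a wild type mean of 47.0 and a heterozygous mean of 47.2. The next gene, Limk2, measured 0.977 and 0.989 of the wild type mean in null replicates 2 and 3. At 17 months the 4 null libraries ranged from 0.939 to 1.26 of the wild type mean for Drg1, from 0.965 to 1.14 for Eif4enif1, from 1.01 to 1.09 for Patz1 and from 0.945 to 1.31 for Pik3ip1. Sfi1 ranged more widely there, at 1.38 and 0.922 in null replicates 1 and 4 and at 0.737 and 0.713 in null replicates 2 and 3.

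**Figure D2:**
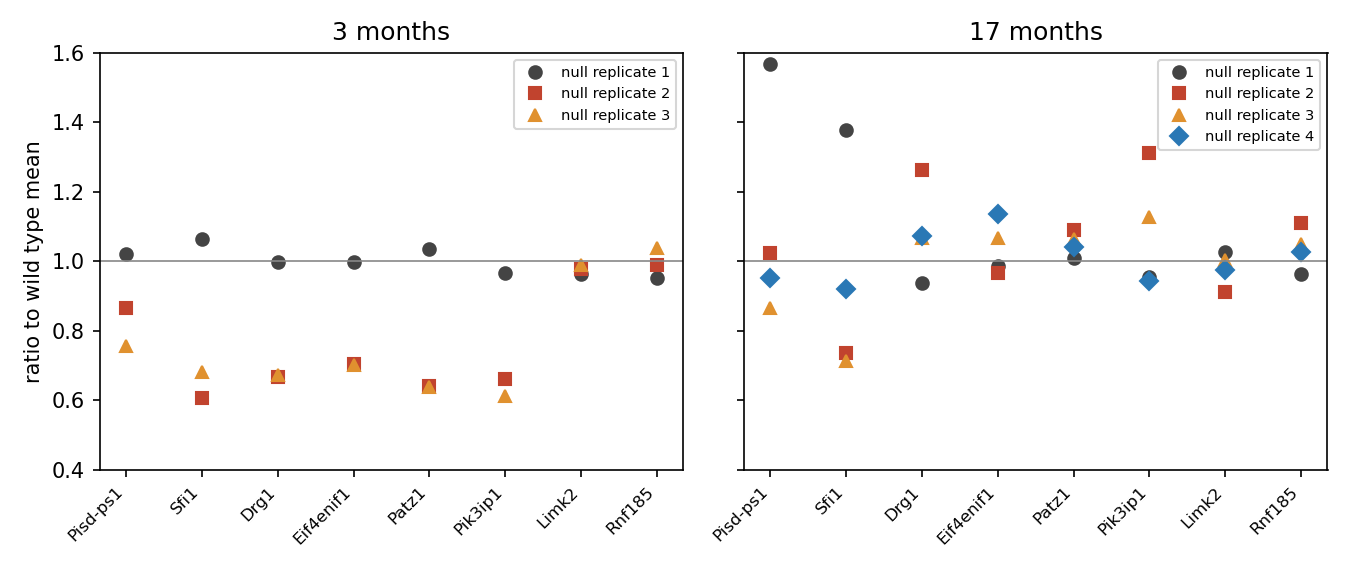
Ratio of each null library to the wild type mean of its age for 8 genes in chromosome order at the start of chromosome 11. At 3 months Sfi1 to Pik3ip1 lie between 0.608 and 0.703 in null replicates 2 and 3 and between 0.968 and 1.06 in null replicate 1.

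Of 26 gene lists tested at 3 months, camera with a preset correlation called 7 in null against wild type cords. Immediate early genes (mean log2 difference 0.15, 17 genes, adjusted p = 0.000747), heat shock and ER stress genes (0.13, 15 genes, adjusted p = 0.000747), erythroid genes (0.34, 9 genes, adjusted p = 0.00118), reactive astrocyte genes (0.12, 15 genes, adjusted p = 0.0160) and endothelial and pericyte genes (0.05, 16 genes, adjusted p = 0.0482) were higher. Oligodendrocyte and myelin genes (-0.06, 20 genes, adjusted p = 0.000747) and cholesterol synthesis genes (-0.05, 16 genes, adjusted p = 0.00132) were lower. Each of these 7 calls had an adjusted p = 0.719 with an estimated correlation, and fry gave 0 after adjustment. Among the immediate early genes, the phosphatase gene Dusp1 (0.18, SE 0.06) and the endothelial transcription factor Klf2 (0.33, SE 0.12) had the smallest p. In the stress list Hspa8 (0.10, SE 0.04) and the ER chaperone Hspa5 (0.23, SE 0.09) did, among the myelin genes Cldn11 (-0.13, SE 0.05) and Mog (-0.10, SE 0.04), and in the cholesterol list Dhcr7 (-0.12, SE 0.04) and Srebf2 (-0.07, SE 0.03).

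Adjusted over the list alone, 5 list members passed at 3 months in null cords. These were the water channel Aqp4 of astrocyte end feet (0.16, SE 0.03), the endothelial Emcn (0.19, SE 0.05), the pericyte gene Rgs5 (0.16, SE 0.05), Mlip in the nerve root list (0.40, SE 0.13) and, on the lower side, Enpp6 of newly forming oligodendrocytes (-0.22, SE 0.06). None of them passed over all genes tested by limma, where only the 2 genes above did. Without null replicate 1, Aqp4 passed over all genes (0.19, limma adjusted p = 0.0487). Single libraries ended some list calls: the heat shock call without null replicate 3 (mean 0.02), the myelin call without wild type replicate 1 (-0.02), the erythroid call without wild type replicate 2 (0.11), the cholesterol call without wild type replicate 3 (-0.02) or null replicate 2, and the reactive astrocyte and endothelial calls each without any of several libraries. Lists of lysosomal, autophagy, microglial, interferon, antigen presentation, complement, inflammatory, motor neuron, synaptic, ALS and FTD, and locus genes were not called (adjusted p from 0.220 to 0.895).

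At 3 months, heterozygous cords differed from wild type cords in the target alone among 13972 genes, and 496 genes had an unadjusted limma p under 0.05. The genes with the smallest p besides it did not pass: the antiproliferative gene Tob2 (8.42 against 6.76 RPKM, log2 difference 0.29, SE 0.06, limma adjusted p = 0.971), the peptide transporter Slc15a2 (0.23, SE 0.05) and Cnbd2 (0.26, SE 0.06) on the higher side, and Phyhd1 (-0.34, SE 0.06, limma adjusted p = 0.372), Lyplal1 (-0.40, SE 0.08) and the sialyltransferase St6galnac5 (-0.30, SE 0.07) on the lower side. Camera called 4 lists: immediate early genes (0.15, adjusted p = 2.30e-05), heat shock and ER stress genes (0.11, adjusted p = 0.0390) and ribosomal protein genes (0.03, adjusted p = 0.00285) were higher, and cholesterol synthesis genes (-0.05, adjusted p = 2.30e-05) were lower. All 4 had an adjusted p = 0.953 with an estimated correlation. Dusp1 (0.19, SE 0.06), Nr4a1 (0.27, SE 0.08) and Hspa1a (0.45, SE 0.22) were among the members with the smallest p, as was Idi1 (-0.10, SE 0.05). Adjusted over the list alone, 0 members passed by limma at 3 months in heterozygous cords. Without heterozygous replicate 3 the immediate early (mean 0.08) and heat shock calls (0.06) were lost, and without heterozygous replicate 1 the ribosomal call (0.01). The heat shock call was lost without any of 5 libraries, and without wild type replicate 3 only the immediate early call remained.

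Null against heterozygous cords at 3 months gave the target (log2 difference -2.76, SE 0.06, limma adjusted p = 9.75e-11) and Plekhm2 (-0.26, SE 0.03, limma adjusted p = 0.0408), with 902 genes at an unadjusted limma p under 0.05. Ldha (0.23, SE 0.04), the sodium pump regulator Fxyd2 (0.64, SE 0.12) and the receptor Gpr139 (0.40, SE 0.08) had the smallest p on the higher side without passing. On the lower side these were Psen2, a catalytic subunit of gamma-secretase (-0.21, SE 0.04), Pagr1a (-0.15, SE 0.03) and Hyal2 (-0.25, SE 0.06). Without null replicate 1 the count was 7, and with quantile normalization, no filter on low values, limma without trend, or only the 2 groups fitted it was 1, Plekhm2 being the gene lost. The Plekhm2 call was also lost without wild type replicate 2 or 3, any heterozygous replicate, or null replicate 2 or 3.

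At 17 months, the target was the 1 gene past the threshold in null against wild type cords among 14164 tested, and 1020 genes had an unadjusted limma p under 0.05. The genes closest to it on the higher side were the transcription factor Zbtb16 (5.08 ± 1.29 against 2.33 ± 0.179 RPKM, n = 4 each, log2 difference 0.95, SE 0.14, limma adjusted p = 0.0655), the membrane progesterone receptor Paqr5 (0.86, SE 0.15, limma adjusted p = 0.122) and the xanthine dehydrogenase gene Xdh (0.90, SE 0.16, limma adjusted p = 0.122). On the lower side were the microRNA gene Mir8094 (-1.48, SE 0.22, limma adjusted p = 0.0655), the lysophosphatidic acid receptor Lpar1 of oligodendrocytes (-0.36, SE 0.06, limma adjusted p = 0.111) and Trim59 (-0.55, SE 0.09, limma adjusted p = 0.122). Plekhm2 measured 34.4 ± 1.27 RPKM in null and 41.1 ± 1.41 in heterozygous cords, and its difference from wild type was -0.23 (SE 0.05, limma adjusted p = 0.202). As at 3 months its null libraries, at most 35.5 RPKM, lay under all other libraries, at least 39.9.

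The count of genes at 17 months moved with how libraries were weighted. With array weights, which gave null replicate 2 a weight of 0.183 and wild type replicate 4 a weight of 0.224, limma called 94 genes (72 higher and 22 lower in null cords), and without null replicate 1 it called 149 (117 higher and 32 lower), of which 84 were shared. Both counts come from overlapping libraries, so the shared genes are not independent support. Of 35 groupings of the null and wild type libraries, the real one included, 11 called as many genes with array weights (highest other 2652). The called genes with the smallest adjusted p by array weights, named after their values were seen, included Zbtb16 (0.98, SE 0.10, limma adjusted p = 0.000811), the lipid droplet coat gene Plin4 (1.64, SE 0.21, limma adjusted p = 0.00864), the ERK phosphatase Dusp6 (0.47, SE 0.06), Xdh (0.88, SE 0.12) and the glucose transporter Slc2a1 (0.65, SE 0.10), with Trim59 (-0.56, SE 0.08) and Fgfr2 (-0.43, SE 0.06) lower.

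Camera called 15 of 27 lists in null against wild type cords at 17 months, 12 higher and 3 lower. Red blood cell genes moved most. The erythroid list was higher by 1.64 (9 genes, adjusted p = 8.34e-11, and adjusted p = 0.384 with an estimated correlation), with 7 members past adjustment over the list alone. Alas2, the first enzyme of haem synthesis in red cells, differed by 2.15 (SE 0.47), and the globin gene Hbb-bt by 2.25 (SE 0.52). Hbb-b2 and Hbb-bt carried identical values in every library and count as 1 measurement. Without Hbb-b1 and Hbb-b2 the list of 7 genes differed by 1.48 (adjusted p = 7.93e-08, and adjusted p = 0.389 with an estimated correlation). All 4 null libraries lay above all 4 wild type libraries, at an exact permutation p of 0.0286 before adjustment.

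Cholesterol synthesis genes were lower in null cords at 17 months by -0.15 (17 genes, adjusted p = 1.21e-09, and adjusted p = 0.384 with an estimated correlation), with 16 of 17 members on the lower side. Adjusted over the list alone, 5 passed, among them the sterol desaturase gene Sc5d (-0.18, SE 0.06) and the sterol demethylase gene Cyp51 (-0.22, SE 0.07). The exact permutation p was 0.0286, and 0.386 after adjustment over the lists, as for the erythroid list. Oligodendrocyte and myelin genes were lower by -0.10 (20 genes, adjusted p = 0.000586, and adjusted p = 0.389 with an estimated correlation). Adjusted over the list alone, 4 passed, among them Ugt8a (-0.45, SE 0.12), Enpp2 (-0.22, SE 0.06) and Opalin (-0.33, SE 0.10). The myelin call was lost without wild type replicate 4 (mean -0.03), which stood apart, and with array weights (-0.04). Motor neuron and cholinergic genes were lower by -0.11 (20 genes, adjusted p = 0.0239, and adjusted p = 0.581 with an estimated correlation), with Mnx1 (-0.38, SE 0.17) and Chodl (-0.40, SE 0.20) the members with the smallest p. That call was lost without wild type replicate 1 or 4 or null replicate 1 or 2, and its mean turned to 0.00729 with array weights.

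**Figure D3:**
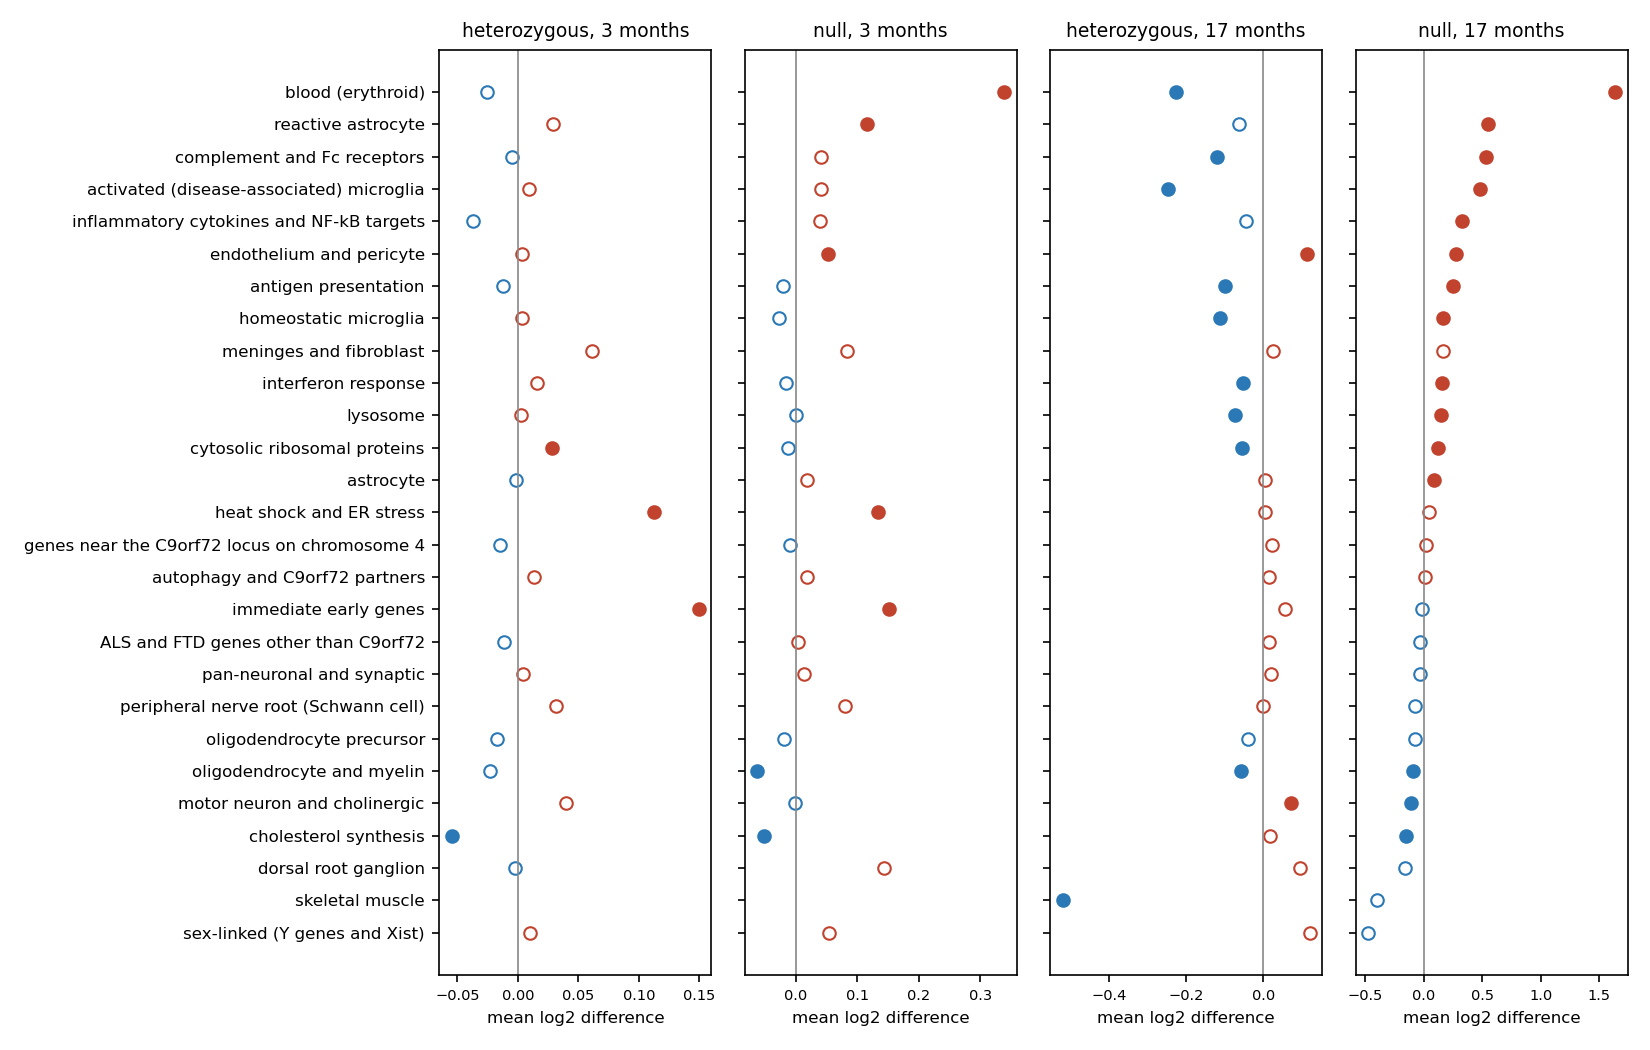
Mean log2 difference from wild type of each gene list for heterozygous and null cords at 3 and 17 months. Filled points passed camera with a preset correlation, open points did not, red is higher and blue lower, and the horizontal scale differs between panels. The erythroid list lies at 1.64 in null cords at 17 months. With an estimated correlation 0 lists passed in any panel.

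Immune and glial lists were higher in null cords at 17 months, together with the library that stood apart, null replicate 2. Complement and Fc receptor genes were higher by 0.53 (17 genes, adjusted p = 2.02e-10, and adjusted p = 0.389 with an estimated correlation), with 5 past adjustment over the list alone, among them complement factor B (Cfb, 0.51, SE 0.11) and the inhibitory Fc receptor Fcgr2b (0.98, SE 0.32). Reactive astrocyte genes were higher by 0.55 (18 genes, adjusted p = 6.58e-09, and adjusted p = 0.389 with an estimated correlation), with Osmr (0.74, SE 0.20), Lcn2 (1.89, SE 0.54) and Cp (0.52, SE 0.16) past adjustment over the list alone. Inflammatory cytokine and NF-kB target genes (0.33, 18 genes, adjusted p = 6.91e-06) and antigen presentation genes (0.25, 17 genes, adjusted p = 1.97e-06) were higher, each with an adjusted p = 0.389 with an estimated correlation. Nfkbia (0.76, SE 0.22), Icam1 (0.73, SE 0.21), Tap1 (0.31, SE 0.09) and H2-Q4 (0.39, SE 0.11) passed adjusted over the list alone. Astrocyte genes were higher by 0.09 (15 genes, adjusted p = 0.0111, and adjusted p = 0.389 with an estimated correlation), including Gjb6 (0.37, SE 0.10) and the glutamate transporter Slc1a3 (0.38, SE 0.11). Without null replicate 2 these 5 calls remained with smaller means: 0.28 for complement, 0.27 for reactive astrocyte, 0.15 for inflammatory, 0.06 for antigen presentation and 0.05 for astrocyte genes.

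The remaining immune lists lost their calls without null replicate 2 alone. Activated microglia genes were higher by 0.48 (23 genes, adjusted p = 1.86e-05, and adjusted p = 0.581 with an estimated correlation), with Cst7 (1.22, SE 0.53) and Gpnmb (1.33, SE 0.64) the members with the smallest p. Interferon response genes were higher by 0.16 (32 genes, adjusted p = 0.000490, and adjusted p = 0.581 with an estimated correlation), lysosomal genes by 0.14 (43 genes, adjusted p = 0.000278, and adjusted p = 0.601 with an estimated correlation), and homeostatic microglia genes by 0.16 (20 genes, adjusted p = 0.0186, and adjusted p = 0.624 with an estimated correlation). Adjusted over the list alone, 0 members of these 4 lists passed by limma. Without null replicate 2 the means were 0.13 for activated microglia, 0.05 for interferon response, 0.03 for lysosomal and 0.03 for homeostatic microglia genes, and all 4 calls were lost. The homeostatic microglia call was also lost without wild type replicate 1 or 2. With wild type replicate 4 left out as well, which was high for microglial and lysosomal genes, the means were 0.32 for activated microglia (adjusted p = 0.000367), 0.12 for lysosomal (adjusted p = 1.12e-06) and 0.13 for homeostatic microglia genes (adjusted p = 0.00706) by camera with a preset correlation, and only the interferon response call stayed lost (0.06, adjusted p = 0.247). The exact permutation p with both libraries left out was 0.3 for activated and homeostatic microglia genes and 0.1 for lysosomal genes, and 0.1 was the smallest possible. With the Y-linked level as a covariate the means were 0.29 for activated and 0.09 for homeostatic microglia genes, and the homeostatic call was lost. Ribosomal protein genes were higher by 0.13 (52 genes, adjusted p = 0.000163, and adjusted p = 0.627 with an estimated correlation), and the mean was -0.01 without null replicate 2. The ribosomal call was also lost without wild type replicate 1 (mean 0.07) and with the length and GC trend removed from each library (0.06, adjusted p = 0.0513). The centred list mean of null replicate 2 was 1.21 for reactive astrocyte and 1.16 for complement genes.

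Endothelial and pericyte genes were higher in null cords at 17 months by 0.27 (16 genes, adjusted p = 1.97e-06, and adjusted p = 0.389 with an estimated correlation). Ly6c1 (0.96, SE 0.23), the VEGF receptor Flt1 (0.38, SE 0.11), Pecam1 (0.41, SE 0.13) and Acta2 (0.55, SE 0.19) passed adjusted over the list alone. The lowest library of this list was wild type replicate 4 and the highest null replicate 2, and with both left out (mean 0.10) or with array weights (0.12) the call was lost. Lists not called were autophagy and C9orf72 partners (0.01, adjusted p = 0.936), synaptic (-0.03, adjusted p = 0.173), oligodendrocyte precursor (-0.08, adjusted p = 0.175), Schwann cell (-0.07, adjusted p = 0.408), dorsal root ganglion (-0.16, adjusted p = 0.162), meningeal and fibroblast (0.16, adjusted p = 0.319), skeletal muscle (-0.40, adjusted p = 0.175), immediate early (-0.01, adjusted p = 0.328), heat shock and ER stress (0.05, adjusted p = 0.936), ALS and FTD genes (-0.03, adjusted p = 0.0821), sex-linked genes (-0.48, adjusted p = 0.328) and genes near the target locus (0.02, adjusted p = 0.889). Members of uncalled lists that passed adjusted over the list alone were Fosl2 (0.38, SE 0.07), Arc (-0.67, SE 0.15) and Jun (-0.29, SE 0.09) of the immediate early genes, Enpp6 (-0.28, SE 0.07) and Lum (-0.39, SE 0.11). Over all lists 41 members passed, and by fry 0 lists passed adjustment.

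**Figure D4:**
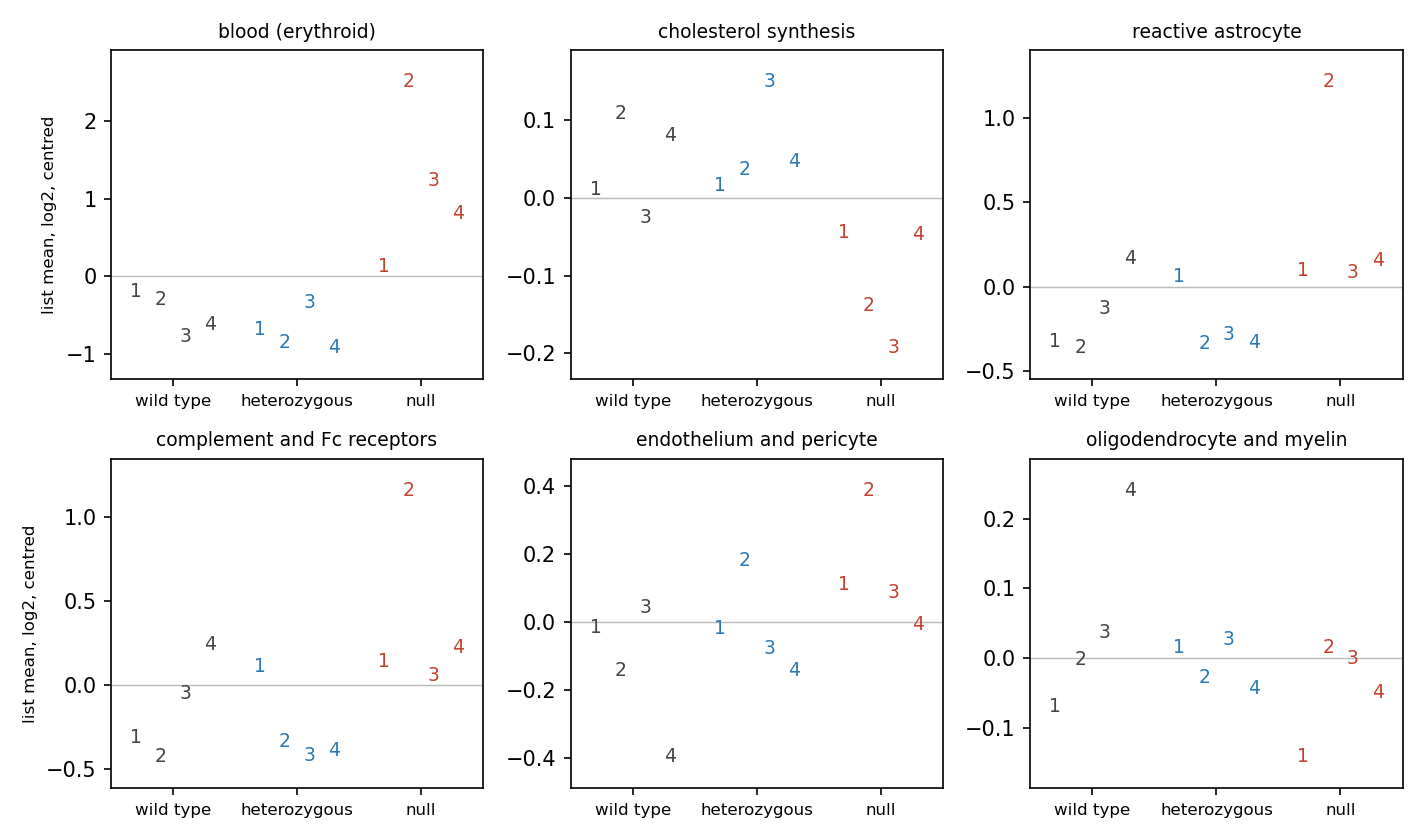
Centred mean log2 level of 6 gene lists in each 17 month library, with replicate numbers as symbols. Null replicate 2 is highest for reactive astrocyte (1.21) and complement genes (1.16), whereas every null library lies above every wild type library for erythroid genes and below for cholesterol synthesis genes.

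Lists of blood-borne white cells had too few members for a test. The neutrophil genes S100a8 and S100a9, chosen after their values were seen, measured 0.558 ± 0.214 and 0.665 ± 0.357 RPKM in wild type and 1.61 ± 2.39 and 1.71 ± 2.39 RPKM in null cords at 17 months (n = 4 each). The higher null means came from null replicate 2 (5.18 RPKM for S100a8 and 5.25 for S100a9). T and NK cell, B and plasma cell and infiltrating myeloid lists had fewer than 3 tested members at both ages, as had skeletal muscle at 3 months, and 0 mitochondrially encoded genes were in the tables used.

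At 17 months, heterozygous against wild type cords gave 0 genes past the threshold by limma among 14164, with 128 at an unadjusted p under 0.05. The smallest p besides the target belonged to the AP-1 subunit Fosl2 (2.02 against 1.59 RPKM, log2 difference 0.27, SE 0.07), Efcab1 (0.24, SE 0.07) and Tmem198 (0.22, SE 0.07) on the higher side and to Mir8094 (-0.85, SE 0.22), Zscan25 (-0.22, SE 0.06) and Spag4 (-0.37, SE 0.10) on the lower side, each with a limma adjusted p of 1.00. Camera called 12 lists. Endothelial and pericyte (0.11, adjusted p = 0.000511) and motor neuron genes (0.07, adjusted p = 0.0257) were higher. Skeletal muscle (-0.52, 3 genes, adjusted p = 0.000288), erythroid (-0.23, adjusted p = 0.0336), activated microglia (-0.25, adjusted p = 0.000259), complement (-0.12, adjusted p = 0.0135), homeostatic microglia (-0.11, adjusted p = 0.000337), antigen presentation (-0.10, adjusted p = 0.0195), lysosomal (-0.07, adjusted p = 0.000259), myelin (-0.06, adjusted p = 0.00121), interferon response (-0.05, adjusted p = 0.0169) and ribosomal protein genes (-0.05, adjusted p = 0.000511) were lower. The calls had an adjusted p = 0.549 with an estimated correlation for skeletal muscle, adjusted p = 0.914 with an estimated correlation for ribosomal proteins, and adjusted p = 0.858 with an estimated correlation for the other 10. Adjusted over the list alone, Fosl2 was the 1 member that passed. Without wild type replicate 4, which stood apart, 5 lists were called, of which 4 were among the 12. The means of the lysosomal (0.0147), complement (0.00626), myelin (0.00441) and ribosomal protein genes (0.0258) then turned positive. With array weights 4 lists were called, 3 of them among the 12. Without wild type replicate 3 the motor neuron mean was 0.00248 and its call was lost, as it was without heterozygous replicate 2 or 4, and the skeletal muscle mean was -0.28 and stayed called. The centred skeletal muscle mean was 1.04 and 0.50 in wild type replicates 3 and 4. In wild type replicates 1 and 2 it was -0.17 and -0.14, within the heterozygous range of -0.40 to -0.13. One member, Pvalb, measured 71.1 RPKM in wild type cords at 3 months against 0.292 for Acta1, so the list need not reflect muscle. The erythroid call was lost without any of 5 libraries, the interferon call without wild type replicate 1 or 3 or heterozygous replicate 3, and the endothelial and ribosomal calls without heterozygous replicate 2 (ribosomal mean -0.00185). The complement call was lost without wild type replicate 3 or heterozygous replicate 3 or 4, and the antigen presentation call without wild type replicate 1 or heterozygous replicate 3.

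Null against heterozygous cords at 17 months gave the target alone (log2 difference -2.26, SE 0.18, limma adjusted p = 0.000220), with 1026 genes at an unadjusted limma p under 0.05. Zbtb16 (0.85, SE 0.14, limma adjusted p = 0.287), the hypoxia-inducible factor subunit Hif3a (1.38, SE 0.26) and Xdh (0.82, SE 0.16) had the smallest p on the higher side without passing. Trim59 (-0.50, SE 0.09), Lpar1 (-0.32, SE 0.06) and Plekhm2 (-0.25, SE 0.05, limma adjusted p = 0.353) did on the lower side. With array weights 54 genes were called, and without null replicate 1 91 genes were called.

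The null effects of the 2 ages, measured in separate mice, correlated weakly across 13647 genes (Pearson r = 0.233, Spearman rho = 0.143, jackknife SE over libraries 0.0820; genes are not independent replicates). At an unadjusted p under 0.05, 59 genes were higher in null cords at both ages against 18.5 expected, and 41 were lower against 16.1 expected. At an unadjusted p under 0.01 there were 8 higher, of which examples were chosen after their values were seen, including the endothelial genes Eng and Edn1, the chemokine Cxcl12, Igfbp7, Plin4 and the phagocytic receptor Mertk, against 1.31 expected, and 4 lower, including Plekhm2, Enpp6 and Pvrl1, against 0.754 expected. Of 26 lists tested at both ages, 0 differed in their null effect between ages after adjustment (permutation within age, smallest adjusted p = 0.522). Even the erythroid list, at 0.34 and 1.64, gave an unadjusted permutation p of 0.117 with so few libraries. The result thus does not show that null effects are equal at both ages.

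Heterozygous and null effects share wild type libraries, which correlates them by construction. At 3 months they correlated at r = 0.473 across genes, against 0.497 in simulated groups without effects (covariance 0.00294 against 0.00305). At 17 months they correlated at r = 0.180 against 0.503 (covariance 0.00272 against 0.00852), and with the wild type libraries split between the comparisons r was -0.217. The jackknife SE over libraries was 0.230 at 3 months and 0.355 at 17 months. Leaving out 1 library moved the 17 month r from 0.0762 (without heterozygous replicate 1) to 0.452 (without wild type replicate 4). These values therefore do not show that heterozygous and null effects diverge.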

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

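The tests of null replicate 2, of sex, of length and GC, of endothelial content and of carryover were chosen after the results they bear on had been seen. The splits of libraries and the test on further glucocorticoid target genes were set beforehand. The bound of 10 times for carryover was set after the ratios were seen.

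A library far from the other 3 of its group was found in 12 of 123 groups of values examined at 17 months. Chance gives about 1 in 20 (5%) for independent groups. These groups were not independent, since lists move together and most of the 12 came from null replicate 2 and heterozygous replicate 1. The count therefore does not measure an excess over chance. Null replicate 2 lay apart from the other null libraries for the lysosomal (centred list mean 0.46), antigen presentation (0.76), complement and Fc receptor (1.16), inflammatory (0.77) and reactive astrocyte lists (1.21). Heterozygous replicate 1, with high Xist, lay apart for activated microglia (0.33), complement (0.11) and reactive astrocyte genes (0.0605). Heterozygous replicate 2 lay apart for skeletal muscle genes (-0.40). Among named genes, Hif3a stood apart in wild type replicate 4 (0.270 RPKM), Mir8094 in null replicate 4 (0.480 RPKM) and Trim59 in null replicate 1 (16.3 RPKM). Of 26 lists, 0 differed between ages in their null effect by permutation (smallest adjusted p = 0.522). With so few libraries this does not show that the effects are equal.

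The first pattern weighed was the higher level of 9 immune and glial lists in null cords at 17 months. Without null replicate 2 the median list kept 34.3% of its difference, and camera with a preset correlation called 5 of the 9. A loss of that size met the prediction written for null replicate 2 as the source. With wild type replicate 4 removed as well, a choice made after seeing the data, the median list kept 69.5% (40.3% to 98.0%) and 8 were called. How far the pattern rests on null replicate 2 is thus not settled. The exact permutation p of the 9 lists ran from 0.114 to 0.429 with all libraries. Without null replicate 2 it ran from 0.143 to 0.914. With both libraries removed it ran from 0.1, the smallest possible, to 0.7. With the Y-linked level as a covariate 8 of the 9 lists were called higher, while the differences shrank from 0.48 to 0.29 for activated and from 0.16 to 0.09 for homeostatic microglia genes, and with array weights as well the activated microglia and interferon calls were lost, so an effect of the sex mix is not excluded. All 9 lists were called after a length and GC trend was removed from each library, which argues against that trend as the whole cause. An effect of genotype on these genes stays open, as does the biology or handling of the mouse of null replicate 2.

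The second pattern was a set of glucocorticoid-responsive genes higher in null cords at 17 months, first noticed as Zbtb16, Plin4, Hif3a and 9 other genes picked because they were high. A further 14 textbook targets listed before their values were seen, such as Sgk1, Fkbp5, Mt1 and Mt2, averaged 0.60 higher, 13 of 14 on the higher side, at an exact permutation p of 0.0857, so glucocorticoid exposure remains a candidate explanation that these libraries do not decide. Without null replicate 2 these 14 targets differed by 0.38 (exact permutation p = 0.114), and null replicate 1 (-0.26 on the centred scale) lay among the wild type libraries, so the part of null replicate 2 is not decided either. The 14 targets exceeded the endothelial list by 0.33 (SE 0.25, exact permutation p = 0.314), which leaves more endothelium open. At 3 months, in separate mice, the same 14 targets averaged 0.18 higher in null cords, 13 of 14 on the higher side. The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, so that age does not decide either. In heterozygous cords these targets averaged 0.08 higher at 3 months (exact permutation p = 0.5) and 0.09 higher at 17 months (exact permutation p = 0.114). Genotype, stress and time of collection stay open as untested.

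The third pattern was the target signal left in null cords at 17 months, between 4.17% and 12.99% of wild type. Carryover from a library high in Xist into one that expresses Y-linked genes, or the reverse, would leave a like share of that transcript. Carryover between libraries alike in these transcripts would not show. The share of target left was at least 50.4 times the leaked share of Xist or Ddx3y in null replicates 1 to 3. That argues against carryover there from libraries that differ in these transcripts. Carryover from libraries alike in them, wild type ones included, stays untested. In null replicate 4 the ratio was 2.11, and a single library with a leak of 1.97% does not decide. Reads from an undeleted part of the gene were not tested.

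Splits of the same libraries into other groups gave these limits. At 3 months 3 against 3 libraries make too few splits (10) for a share under 0.05. The real and highest other counts were 2 and 0 genes for null against wild type (1 split as large), 1 and 0 for heterozygous against wild type (1), 2 and 4 for null against heterozygous (2), 7 and 9 lists for null cords (5), and 4 and 9 lists for heterozygous cords (10). At 17 months, with 35 splits, chance could not be excluded for the 1 gene of null against wild type as a count (4 splits as large, highest other 2564), for 94 genes with array weights (11, highest other 2652), for 15 lists in null cords (5, highest other 17), for 12 lists in heterozygous cords (8, highest other 15) or for 54 genes of null against heterozygous with array weights (3, highest other 214). For heterozygous against wild type 0 genes were called, so that the splits (35, highest other 0) test nothing. The split that called 2564 genes set wild type replicates 1 to 3 and null replicate 1 against wild type replicate 4 and null replicates 2 to 4. On the first principal component these sides lay at -12.3 to -8.00 and at 6.33 to 38.0. This structure of the 17 month samples is not genotype but overlaps it. Differences between null and wild type cords at 17 months are therefore partly confounded with it. For null against heterozygous at 17 months the 1 gene was the target itself (1 split, highest other 0). Its level follows the genotype that defines the groups, so these splits test nothing about other genes. For the correlation of null effects between ages of 0.233, only the real pair among 100 drawn pairs of splits lay as far from 0 (highest other 0.187). Such a value was thus uncommon among the drawn pairs. The 3 month side has only 10 splits, and the 17 month side overlaps the structure above. Whether genotype underlies the correlation is therefore not decided.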

How the results depend on the processing

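Alternatives that combine array weights with other changes, remove both libraries that stood apart, or remove a length and GC trend were chosen after seeing the data, as were array weights, median centring and the Y-linked covariate for gene lists. Of the alternatives of counts and main values, 381 left the result on its side of the threshold or within 1.5 times, 43 moved a count or value and 1 made a result stronger; among single genes and lists 5270 were unchanged, 159 lost and 69 gained a call, and 34 turned direction. A list is counted as turned where its mean or the direction of its test changed, since the sign of these differed for some lists near 0; this way of counting was also chosen after seeing the values. The cause was not tested. Null against wild type at 3 months gave 1 gene with no filter on low values, without limma's trend and robust fit, or with only the 2 groups, Plekhm2 being the gene lost. With the replicate block it gave 5, among them Igfbp7 (limma adjusted p = 0.0333) and Snora81 (limma adjusted p = 0.0480). Without 1 library it gave 1 to 8. The numbers do not clearly pair the libraries (5 of 9 pairs correlated over 0.1 at 3 months, all of them positive, from 0.00444 to 0.203, and 3 of 12 at 17 months, from -0.472 to 0.547). Null against heterozygous at 3 months gave 1 with quantile normalization, no filter, plain limma or only the 2 groups, and 1 to 7 without a library. At 17 months null against wild type gave 94 with array weights, 56 with array weights and both outlying libraries removed, 102 with array weights and the Y-linked covariate, and 1 to 149 without a library; null against heterozygous gave 54, 25 and 131, 2 with the length and GC trend removed, and 1 to 91. With only the 2 groups, heterozygous against wild type at 17 months gave 1 gene, the target (-0.85, then past the threshold). With an estimated correlation 0 lists were called in each comparison. Heterozygous cords had 1 to 5 lists at 3 months and 5 to 14 at 17 months without a library; at 17 months 4 with array weights, 5 with both outlying libraries removed, 4 with both changes, and 5 with array weights and the covariate. Splitting the wild type libraries moved the correlation of heterozygous and null effects at 17 months to -0.217. Directions that turned at 17 months were all near 0. In null cords these were Nefl with both libraries removed (0.00908), with array weights as well (0.0465) and with array weights and the covariate (0.00683); the motor neuron list with array weights (0.00729), both libraries removed (0.0224), both changes (0.0466) and weights with the covariate (0.0452); and the ribosomal list without a library (-0.0110 to 0.239). In heterozygous cords with weights and both libraries removed these were Pdgfrb (-0.0142), Rps3 (0.0104), Rps6 (0.00524) and the lysosomal (0.0201), complement (0.00153), myelin (0.00129), endothelial (-0.0241) and ribosomal lists (0.0441). With weights alone they were the lysosomal (0.00738), endothelial (0.00129, where only the test turned) and ribosomal lists (0.0202), and with weights and the covariate the lysosomal (0.0145), complement (0.0115), endothelial (-0.00836) and ribosomal lists (0.0311). With both libraries removed they were the lysosomal (0.0147), complement (0.00626), myelin (0.00441) and ribosomal lists (0.0258). Without a library they were Isl2 (-0.0277 to 0.249), Pvalb (-0.138 to 0.00397) and the lysosomal (-0.113 to 0.0147), complement (-0.243 to 0.00626), myelin (-0.0988 to 0.00441), ribosomal (-0.111 to 0.0258) and interferon lists (-0.0921 to -0.00148, where only the test turned). A count test on recovered reads, a choice among repeated symbols (none remained) and a Y-linked covariate at 3 months (range 0.27) were not run. Depth was unknown, so it sets no limit that can be given.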

Other observations

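No tests of explanations are given in this part, and its genes, apart from Plekhm2 and Lpar1, were singled out after their values were seen. At 3 months, null replicate 1 alone carried transcripts of brown fat and other adipose tissue: Fabp4 (52.5 RPKM, highest other library 0.534), Ucp1 (15.6, highest other 0.119), Cox8b (14.2, highest other 1.93), Pck1 (7.27), Agpat2 (4.80) and Adipoq (3.02). Null replicate 2 alone carried the Schwann cell gene Prx (1.56 RPKM, highest other 0.187). At 17 months null replicate 3 alone was high for Fgf21 (3.83 RPKM, highest other 0.162). Most of these genes were under the expression floor in the other libraries and do not enter the tests.

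The 5 neighbouring genes on chromosome 11 that were lower in null replicates 2 and 3 at 3 months sit in a block that ends between Pik3ip1 and Limk2. Pisd-ps1, before the block, measured 0.865 and 0.757 of the wild type mean in these libraries. No DNA data were analysed here.

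Plekhm2 lies on the chromosome of the target, 106 Mb away.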
